A study of Homo sapiens with 11 samples.

How the data were processed

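RNA of 11 DLD1 samples was measured on 11 one-colour Agilent arrays, 3 of parental, 4 of irinotecan-resistant and 4 of curcumin-treated resistant cells. Groups and replicate numbers came from the sample titles, which the description and characteristics fields match. The source field carries, on every sample, text on a breast-derived culture that conflicts with those fields; it was not used, and markers of mammary and other cell types were included among the gene lists. Per the labels' protocols, total RNA was extracted with phenol and chloroform and Cy3-labelled from 100 ng with a low-input amplification kit. The arrays were scanned and read with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes and the file headers.

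The scanner files deposited by the authors hold linear signal intensities per spot. The processed signal has its background subtracted by that software, per the file headers, and is not normalized between arrays. The authors' deposited table holds log2 values; its method is not given in the sources used here. Its ranks within each array equal those of the median spot signal (rank correlation 1), its columns have nearly the same sorted values with medians from 6.24 to 6.28, and it shows no sign of background subtraction, so a scale of log2 and a between-array normalization close to quantile are read from the values. It was used only as an alternative.

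Each array had 60901 features that are not controls, for 58201 probes. The reference gene table (assembly GRCh38) gave a symbol to 35032 probes (60.2%), matched on accession without version; the other probes kept the array's name. The array was designed on another build (hg19, per the file headers), so no positions are given. Spots flagged as outliers were left out, and spots of 1 probe were averaged. Log2 processed signal was scaled by subtracting each array's 75th percentile over the 12078 probes well above background on all arrays, because under 50% of spots were. Each gene was represented by its probe with the highest mean signal. A gene was tested if well above background on every array of at least 1 group, which left 18889 genes, 14405 of them with a symbol. A gene not well above background on any array of 1 group has a bound ("at least N-fold"): the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own. Such genes were counted as changed with signal above background only if the bound kept the direction.

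The 3 groups were fitted together in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with no covariate, and genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided (8 residual and 3.31 prior degrees of freedom). The comparisons were resistant against parental, curcumin against resistant and curcumin against parental. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 28 of 31 lists with enough genes tested. With the estimated correlation no list passed in any comparison. The lists, fixed before the data were examined, covered irinotecan handling, drug efflux, NRF2, ATF4, endoplasmic reticulum chaperones, heat shock, metallothioneins, AHR, p53, DNA replication, mitosis, DNA repair, the BCL2 family, mesenchymal and epithelial genes, intestinal differentiation, WNT and stem genes, NF-kB, interferon, cholesterol and fatty acid synthesis, hypoxia and glycolysis, MAP kinase output, ribosome biogenesis, autophagy and lysosome, iron and ferroptosis, housekeeping genes and markers of mammary, fibroblast, leukocyte and endothelial cells. RNA classes and lists of short-lived and long-lived mRNAs were written after the data were seen.

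Named genes followed a rule fixed before the data were examined. They are, per main comparison, the 7 largest rises and falls among called genes measured on every array of both groups and moving 1 way on each array, the 3 largest bounds each way, up to 4 members of each list that passed and of the irinotecan, efflux and NRF2 lists, and a fixed panel of drug-response genes; for curcumin against parental, 3 each way; for reversal, the 5 each way with the largest smaller change. Only symbols that are gene names were taken, and text on a list may name its members. The text leaves out 2 genes that met the rule. Differences of single array values were tested with exact two-sided permutation tests.

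Alternatives chosen before the data were examined were quantile normalization, median centring, normexp background correction (offset 50), the authors' table, no filter, only genes well above background everywhere, the mean of probes, each probe on its own, slide and replicate number as blocks, each slide alone, only the groups compared, array weights, a trended robust variance, an adjusted p under 0.01, a 1.5-fold threshold and leaving out each replicate. The files hold a median spot signal but no mean, so normexp used the median. Scaling to the 8 spike-in probes, the percentile over all probes and the count with signal above background were added after seeing the data. The fit was tested on simulated data with 18889 genes, each with the same spread in all groups. It recovered 49%, 56% and 43% of genes changed by 1 log2 unit and 95%, 96% and 98% of those changed by 2, in the order of the comparisons above, with 7.10%, 4.40% and 5.37% of calls false. Versions of other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.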

Results

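Gene expression was measured on 11 one-colour microarrays of DLD1, an established human colorectal carcinoma cell line. The parental cells had 3 arrays. Cells selected in rising concentrations of irinotecan until they grew in 20 µM had 4 arrays, as did these resistant cells after 48 h of curcumin at its half-maximal inhibitory concentration. Irinotecan is a prodrug whose active form traps DNA topoisomerase I on DNA, and curcumin is a polyphenol of turmeric. The series text calls the resistant and the treated samples biological replicas. Nothing states this for the parental samples, so the spread between their arrays may be technical. The fit pools 1 spread per gene over the 3 groups, so its p-values do not measure the spread of any 1 group. Spreads could differ: the gene TXNIP had an SD of 1.62 on parental and 0.12 on resistant arrays. Of the 18889 genes tested, 10217 were well above background on every array. The share of spots well above background was 42.9% to 45.3% on the parental and resistant arrays and 24.3% to 30.8% on the curcumin arrays, and the number of arrays limits the precision of every value. Each group had its own places on both slides, so place and group cannot be separated in any comparison.

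The curcumin arrays carried far less signal from genes, while the signal of their spike-ins, control RNAs added in a fixed amount, changed little. The 75th percentile of the gene probes was 8.55 ± 0.41 (SD, n = 4) in log2 units on the curcumin arrays and 11.51 ± 0.03 (SD, n = 4) on the resistant arrays, a difference of 7.83-fold. In an exact two-sided permutation test this gave p = 0.0286, the smallest value that 4 arrays against 4 allow. The spike-in probes differed by -0.07 log2 units (exact permutation p = 0.543). Against the parental arrays the gene signal was 8.14-fold lower (exact permutation p = 0.0571, the smallest value that 4 against 3 arrays allow). The spike-in probes differed there by -0.29 log2 units, with the same p in this test. All fold changes below are therefore relative to the bulk of the genes on each array, and a change relative to the spike-ins lies 2.90 log2 units lower in curcumin against resistant cells and 2.73 lower in curcumin against parental cells.

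**Figure D1:**
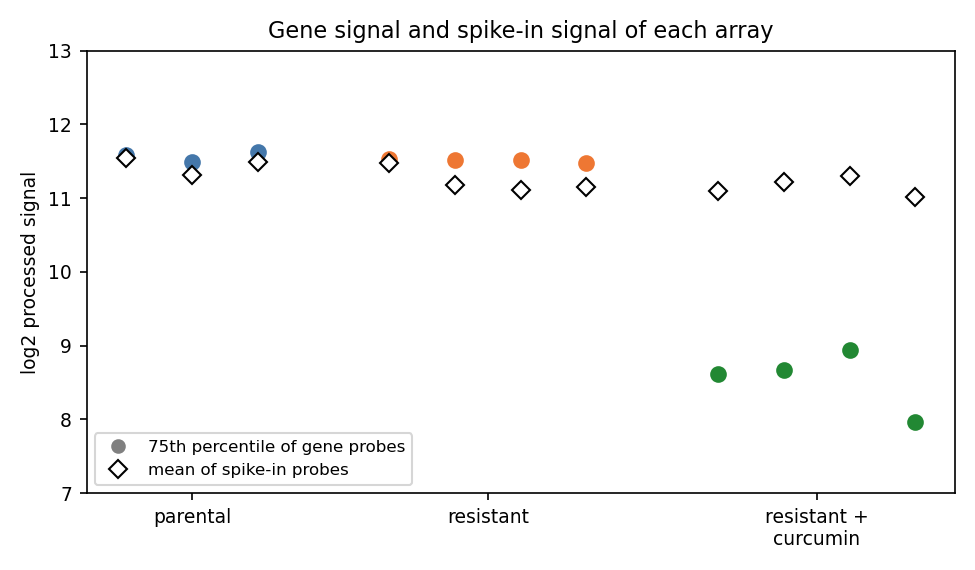
Log2 processed signal (vertical axis) of each array in the 3 groups: filled points give the 75th percentile of the gene probes detected on all arrays, open diamonds the mean of the spike-in probes. The gene signal of the 4 curcumin arrays lies near 8.55, against 11.51 on the resistant arrays, while the spike-in signal stays near 11.16 and 11.23.

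The comparison of resistant with parental cells asks what differs in cells selected in irinotecan. Among the largest falls in the resistant cells were 4 immediate early genes, a group not tested as such: FOS, a transcription factor subunit, was 21.2-fold lower. Its partner JUN was 11.2-fold lower, FOSB 14.7-fold and the MAP kinase phosphatase DUSP1 10.3-fold. Inducible heat shock genes were lower as well, led by HSPA1B, an HSP70, at 7.72-fold, with a scaled log2 signal of -0.74 ± 0.14 (SD, n = 4) against 2.21 ± 0.93 (SD, n = 3). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 5.14-fold higher and GGACT 6.27-fold higher. In limma's test, 1871 of 18889 genes passed an adjusted p of 0.05, 1136 higher and 735 lower, and 973 of them changed at least 2-fold.

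The other large falls among genes measured on every array were in DUOX2, a hydrogen peroxide-producing oxidase (log2 fold change -3.29, SE 0.46, adjusted p = 0.00288), TXNIP, an inhibitor of thioredoxin (-2.95, SE 0.56, adjusted p = 0.0106), and HSPA1B (-2.95, SE 0.34, adjusted p = 0.00112). Leaving out 1 array moved TXNIP between -3.61 and -2.05 and DUOX2 between -3.80 and -2.63. The fall of FOS had an SE of 0.35 and an adjusted p of 0.000163. The rises were smaller: CCDC121 by 2.41 (2.03 to 3.02 without 1 array; GGACT, at 2.65, 2.03 to 3.14), the small Cajal body RNA SCARNA20 by 2.40, the long non-coding RNA SLC20A1-DT by 2.20, MYOM2 by 2.12 and PEX11G by 2.11 log2 units, with adjusted p from 0.000698 to 0.00439. Genes not well above background in 1 group have only a bound, which holds under the background subtraction used here. SOD3, the extracellular superoxide dismutase, was at least 6.66-fold lower in resistant cells (adjusted p = 0.000583), the small nucleolar RNA SNORD75 at least 4.63-fold and SPRR2C at least 4.23-fold lower. LEP, which encodes leptin, was at least 4.68-fold higher (adjusted p = 0.000176), DYNC1I1 at least 3.47-fold and CCK at least 3.06-fold higher. In the authors' table, with no sign of background subtraction, SOD3 had -1.04, LEP 0.76 and CCK 0.48 log2 units, below these bounds.

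Of 17 heat shock genes tested, 11 fell and none rose, and 14 fell when adjusted over the list alone. HSPH1 fell by 1.60, DNAJA1 by 1.61 and HSPA8 by 1.95 log2 units (camera adjusted p = 4.52e-12 for the list; adjusted p = 0.257 with an estimated correlation). Of 19 genes of MAP kinase output, 5 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone. EGR1 fell by 1.60 and ETV1 rose by 1.34 (camera adjusted p = 0.0286; adjusted p = 0.672 with an estimated correlation). This list call was lost in 7 of 27 alternatives, and the list's median against parental replicate 1 alone was 0.29, against -0.69 and -0.39 for replicates 2 and 3. Of 16 hypoxia and glycolysis genes 3 fell, as they did when adjusted over the list alone: ADM by 2.08, ANGPTL4 by 2.62 (-3.72 to -1.85 without 1 array) and PFKFB3 by 1.02 (camera adjusted p = 0.00119; adjusted p = 0.672 with an estimated correlation). These 3 are inducible genes that other stimuli than hypoxia also drive, and NDRG1 had a value of -1.18 (adjusted p = 0.146; -1.88 to -0.43 without 1 array, and called without parental replicate 1 and with array weights). The list call was lost without parental replicate 2 (median -1.51 against that array, -0.13 and -0.30 against replicates 1 and 3), and the calls of ANGPTL4 and PFKFB3 in 14 and 12 of 26 alternatives, the slide block among them. Of 14 intestinal differentiation genes 1 fell, CEACAM6 with -2.33, and 2 fell when adjusted over the list alone, while CEACAM5, above background on 1 of 4 resistant arrays, had -2.07 (-2.73 to -1.37 without 1 array, and called without parental replicate 1), LGALS4 -1.10 and CA2 -0.91 (camera adjusted p = 0.0286; adjusted p = 0.45 with an estimated correlation). Of 15 housekeeping genes 1 fell, ACTB by 0.76 (adjusted p = 0.00712), and 2 when adjusted over the list alone, while GUSB had -0.51, TFRC -0.70 and POLR2A -0.32 (camera adjusted p = 0.0286; adjusted p = 0.578 with an estimated correlation). The calls of the intestinal and the housekeeping list were each lost in 11 of 27 alternatives.

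Of 23 genes of the ATF4 amino acid stress response 2 rose, PCK2 and PSAT1 (1.14, adjusted p = 0.0198), the same count as when adjusted over the list alone. PHGDH had 0.70 and MTHFD2 0.89 (camera adjusted p = 0.00193; adjusted p = 0.705 with an estimated correlation). Of 19 chaperones of the endoplasmic reticulum 1 rose, SDF2L1 by 1.13, also when adjusted over the list alone, while HSPA5 had 1.52 (0.76 to 2.31 without 1 array), HYOU1 1.35 (0.88 to 2.07) and MANF 0.90 (camera adjusted p = 0.0222; adjusted p = 0.732 with an estimated correlation). Both calls were lost without parental replicate 1, at camera adjusted p = 0.405 and 0.324. On slide 2 alone the chaperone list pointed the other way, with a mean of -0.17.

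None of 9 irinotecan-handling genes passed the test, over all genes or adjusted over the list alone (camera adjusted p = 0.659). TOP1, the drug's target, had a log2 fold change of -0.22 (SE 0.15, adjusted p = 0.387), the activating carboxylesterase CES2 0.52 (SE 0.21, adjusted p = 0.137), TDP1, which repairs trapped topoisomerase, 0.40 (adjusted p = 0.199), UGT1A6 0.43 (adjusted p = 0.122) and GUSB -0.51 (adjusted p = 0.0555). The fall of GUSB passed in 7 of 26 alternatives, median centring and the authors' table among them. Among 13 drug efflux transporters 2 rose, ABCB4 by 1.07 (adjusted p = 0.0244) and ABCC10 by 0.86 (adjusted p = 0.0457), as when adjusted over the list alone (camera adjusted p = 0.264), but of 25 alternatives 8 lost the call of ABCB4 and 17 that of ABCC10, the slide block among the latter. ABCB1 had -0.35 (adjusted p = 0.447), ABCC1 0.14 (adjusted p = 0.671), ABCC2 0.90 (adjusted p = 0.197) and ABCC5 0.34 (adjusted p = 0.136). The probe of ABCG2, a transporter of the active drug, was not well above background on any array, and no probe was named UGT1A1. None of 27 NRF2 target genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.781), with PGD at 0.64, GCLC at 0.59 and AKR1B10 at 1.33 (0.86 to 1.77 without 1 array). The rise of GCLC passed in 5 of 26 alternatives and that of AKR1B10 in 4 of 25, normexp among both.

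The number of genes called depended on single arrays: it was 677 without resistant replicate 3, 995 without resistant replicate 4, 1009 without parental replicate 2, 1017 without resistant replicate 2 and 2852 without parental replicate 1. With the slide as a block 1553 genes passed. Slide 1 alone (2 arrays against 2) gave 69 and slide 2 alone (2 against 1, the lone array taken to vary like the other groups) gave 0. The share of calls that were higher, 60.7% here, was 46.3% with arrays centred on the median, 46.8% with quantile normalization, 50.6% in the authors' table, 43.45% with the percentile over all probes and 81.75% with scaling to the spike-ins, which moved the median of all genes from 0.05 to 0.22. The 7 lists called were no more than other groupings of the same arrays gave, up to 13. The counts of members describe the lists but are no independent support, since members of a list can be correlated.

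**Figure D2:**
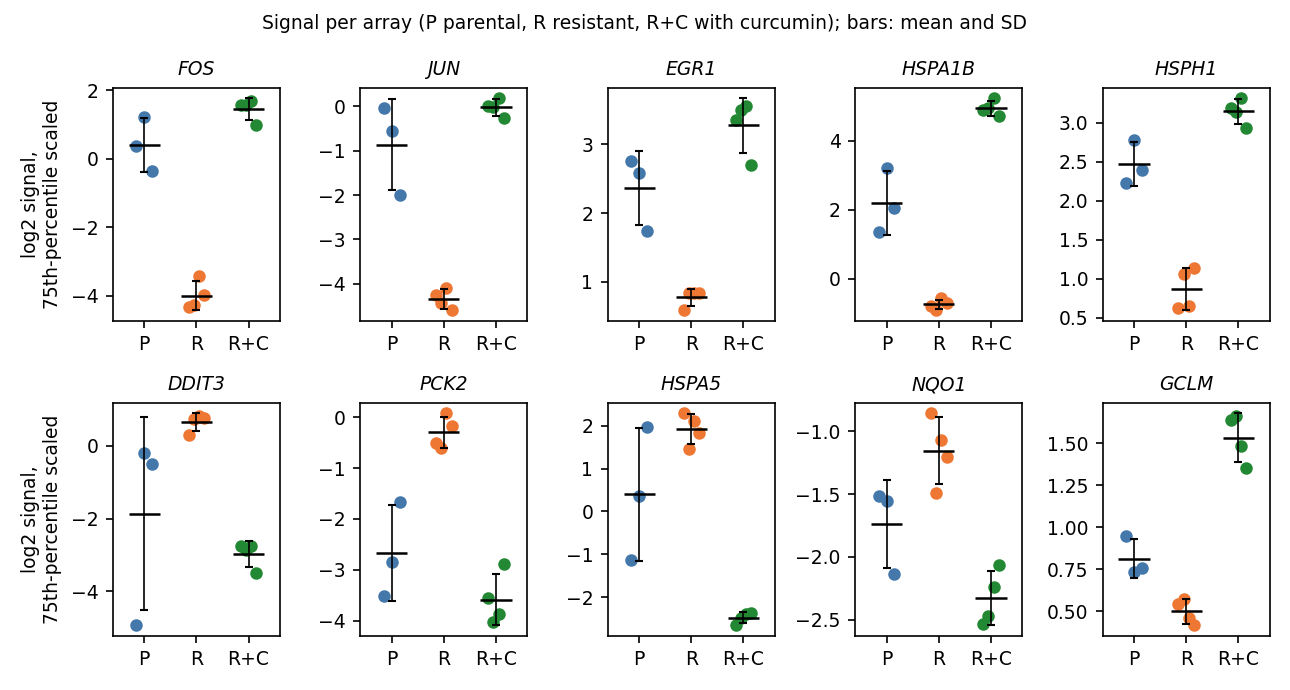
Scaled log2 signal (vertical axis, relative to the array's 75th percentile) of 10 genes on each array of the parental (P), resistant (R) and curcumin-treated resistant (R+C) groups; lines and error bars give mean and SD. JUN lies at -4.34 in resistant cells against -0.86 in parental and -0.02 in treated cells, and HSPA5 at 1.92 in resistant against -2.48 in treated cells.

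The comparison of curcumin-treated with untreated resistant cells asks what 48 h of curcumin changes. Relative to the bulk of the genes, all 17 heat shock genes rose, with HSPA1B 51.3-fold and its near-identical copy HSPA1A, above background on 3 of 4 resistant arrays, 37.3-fold higher. Genes of the amino acid and endoplasmic reticulum stress responses fell: CHAC1, which degrades glutathione, was 28.5-fold lower, DDIT4, an inhibitor of mTORC1, 24.1-fold and HSPA5, the chaperone BiP, 21.1-fold lower. Among genes measured on every array of both groups, the highest rises were in small non-coding RNAs such as RNU6ATAC of the minor spliceosome, 377-fold higher. FOS and JUN, low in resistant cells, rose after curcumin by 5.45 and 4.32 log2 units. In limma's test 13183 genes passed, 5783 higher and 7400 lower, and 8918 changed at least 2-fold. Of the 13183, 10495 had signal above background and a bound that kept the direction, 4003 higher and 6492 lower.

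The other leading falls were in NUPR1, a stress-induced transcriptional regulator (-4.17, SE 0.56, adjusted p = 4.16e-05), S100P (-4.11, SE 0.49, adjusted p = 1.62e-05), MAT2A, which makes S-adenosylmethionine (-3.87, SE 0.14, adjusted p = 6.01e-09), and PHLDA1 (-3.86, SE 0.30, adjusted p = 6.58e-07). The small nucleolar RNA SNORA20 rose by 8.25, the vault RNA VTRNA2-1 by 7.43 and the U1 variant RNVU1-18 by 6.86 log2 units, with SEs of 0.21, 0.46 and 0.15. Among longer transcripts the non-coding CASC15 and NALF1-IT1 rose by 6.21 and 6.20. As bounds, VTRNA1-2 was at least 280-fold, VTRNA1-1 at least 192-fold and RFPL4AL1 at least 147-fold higher, while TMEM63C was at least 12.7-fold, DICER1-AS1 at least 9.92-fold and PDXDC2P-NPIPB14P at least 9.31-fold lower. VTRNA1-1 had 5.27 log2 units in the authors' table and TMEM63C -1.51 under normexp, which adds an offset, both below these bounds. RNVU1-18 belongs to a family of near-identical copies, so its probe may read several.

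All 17 heat shock genes also rose when adjusted over the list alone, among them HSPH1 by 2.28 and HSPB1 by 1.82, though over all genes 14 rose with quantile normalization and in the authors' table, where HSPB1 had 0.12 and 0.13 (camera adjusted p = 2.8e-07; adjusted p = 0.391 with an estimated correlation). Of 23 ATF4 stress genes 21 fell and 2 rose, also when adjusted over the list alone. The cystine transporter SLC7A11 fell by 5.10, PCK2 by 3.28, DDIT3, the transcription factor CHOP, by 3.63, and the amino acid transporter SLC7A5 by 1.96, while ATF3 rose by 1.93 and SHMT2 by 0.51 (camera adjusted p = 0.000638; adjusted p = 0.673 with an estimated correlation). SLC7A11 was well above background on 3 of 4 curcumin arrays. Of 19 endoplasmic reticulum chaperones 15 fell and 2 rose, also when adjusted over the list alone: SEL1L fell by 3.55 and XBP1 by 2.31, and CANX and SEC61B rose by 0.84 and 0.44 (camera adjusted p = 0.0139; adjusted p = 0.673 with an estimated correlation). Of 9 metallothionein-list genes 7 rose, also when adjusted over the list alone, with MT2A at 1.74, MT1B at 1.95, MT1A at 1.38 and MT1L at 1.89, of which MT2A lost its call with quantile normalization (0.27) and in the authors' table (0.31) (camera adjusted p = 0.0144; adjusted p = 0.489 with an estimated correlation). Probes of this family can share targets.

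Of 33 DNA replication genes 17 rose and none fell, and 16 rose when adjusted over the list alone. LIG1 rose by 1.46, TK1 by 1.66, MCM7 by 1.62 and CDT1 by 1.48, but with quantile normalization the calls of TK1 (0.49) and MCM7 (0.88) were lost, that of TK1 also in the authors' table (0.46) (camera adjusted p = 0.00762; adjusted p = 0.738 with an estimated correlation). Of 20 ribosome biogenesis genes 9 rose and 1 fell, also when adjusted over the list alone, with NPM1 at 2.28 (0.36 with quantile normalization), RRP9 at 2.22, NOP58 at 2.20 and BOP1 at 2.04 (camera adjusted p = 0.0385; adjusted p = 0.673 with an estimated correlation). Of 27 alternatives, 7 lost this list call and 1 turned it, and 3 lost and 1 turned that of DNA replication. Of 13 drug efflux transporters 8 fell and none rose, also when adjusted over the list alone. ABCC5 fell by 2.22 and MVP, the major vault protein, by 1.59, ABCB4 was at least 1.30-fold and ABCC6 at least 1.53-fold lower, and ABCB1 had -0.51 (adjusted p = 0.0962; camera adjusted p = 0.0139 for the list; adjusted p = 0.391 with an estimated correlation). Of the probes measured, 2 of 3 for ABCC5 and 3 of 4 for ABCC6 pointed down. Under normexp background correction the median of this list turned to 0.81, ABCB4 to 1.19 and ABCC6 to 0.97.

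Of 9 irinotecan-handling genes 4 fell and none rose with signal above background, and 3 fell when adjusted over the list alone (camera adjusted p = 0.633). UGT1A6 fell by 1.23, TOP2A by 1.67 and SLCO1B3 by 0.84, the last at 0.12 under normexp, and TOP1 had 0.06 (adjusted p = 0.722). Of 27 NRF2 targets 14 fell and 6 rose, also when adjusted over the list alone (camera adjusted p = 0.246). The ferritin heavy chain FTH1 rose by 2.45, thioredoxin TXN by 1.67 and GCLM, a subunit of the glutathione-making ligase, by 1.03, while AKR1C3 fell by 3.71, AKR1B10 was at least 8.28-fold lower and NQO1 fell by 1.17. With quantile normalization FTH1 had 0.28, and the call of TXN was lost at 0.30. HMOX1 had -0.16 (SE 0.16, adjusted p = 0.393), and CDKN1A, with 1 of 4 curcumin arrays above background, 0.65 (adjusted p = 0.257). The call of CDKN1A was gained under normexp, and its values reached 2.20 over the alternatives.

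**Figure D3:**
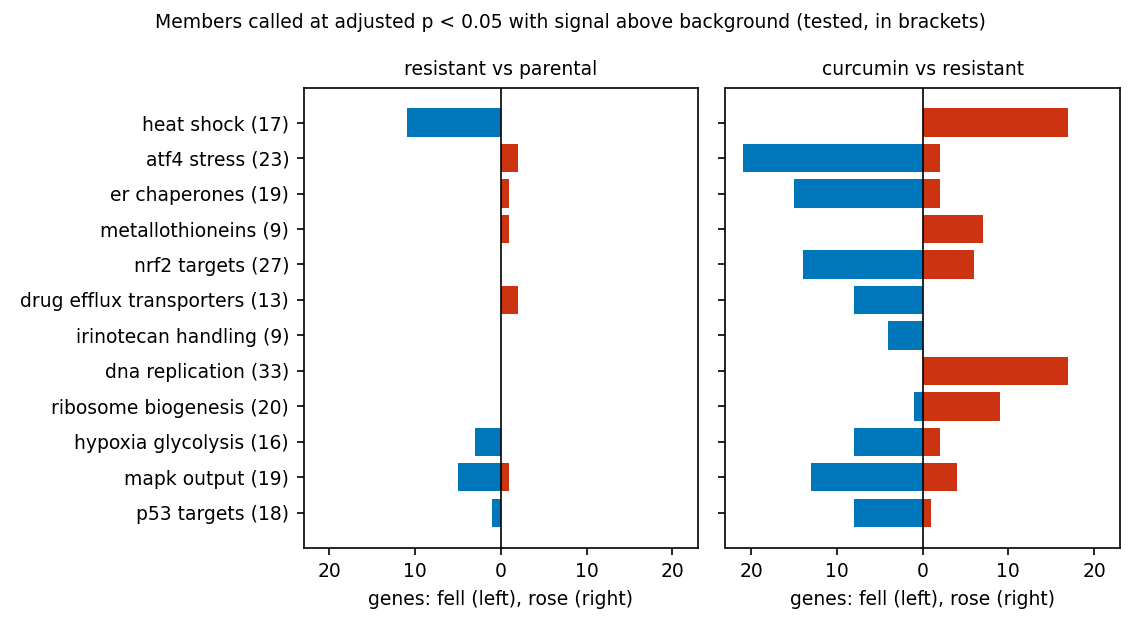
Number of genes of 12 lists (tested members in brackets) that fell (left, blue) or rose (right, red) with signal above background, in resistant against parental and in curcumin-treated against resistant cells. Heat shock genes fell in 11 of 17 cases in resistant cells and rose in 17 of 17 after curcumin; ATF4 stress genes fell in 21 of 23 after curcumin.

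RNA classes, which were defined after the data were seen, moved apart. Relative to the bulk of the genes, 57 of 58 replication-dependent histone genes, whose mRNAs end without a poly(A) tail, rose, with a median of 2.94 over those measured in both groups. All 13 small nuclear RNAs rose (median 5.47), as did 123 of 193 small nucleolar RNAs (median 2.35, 8 fell), all 4 vault RNAs and both RNA subunits of the RNases P and MRP. Other protein-coding genes had a median of -0.23, and 77 of 78 ribosomal protein genes rose (median 1.88), a rise that vanished with quantile normalization (-0.08 over all tested) and in the authors' table (-0.05). Relative to the spike-ins the histone median was 0.04, that of small nuclear RNAs 2.57 and that of other protein-coding genes -3.13.

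**Figure D4:**
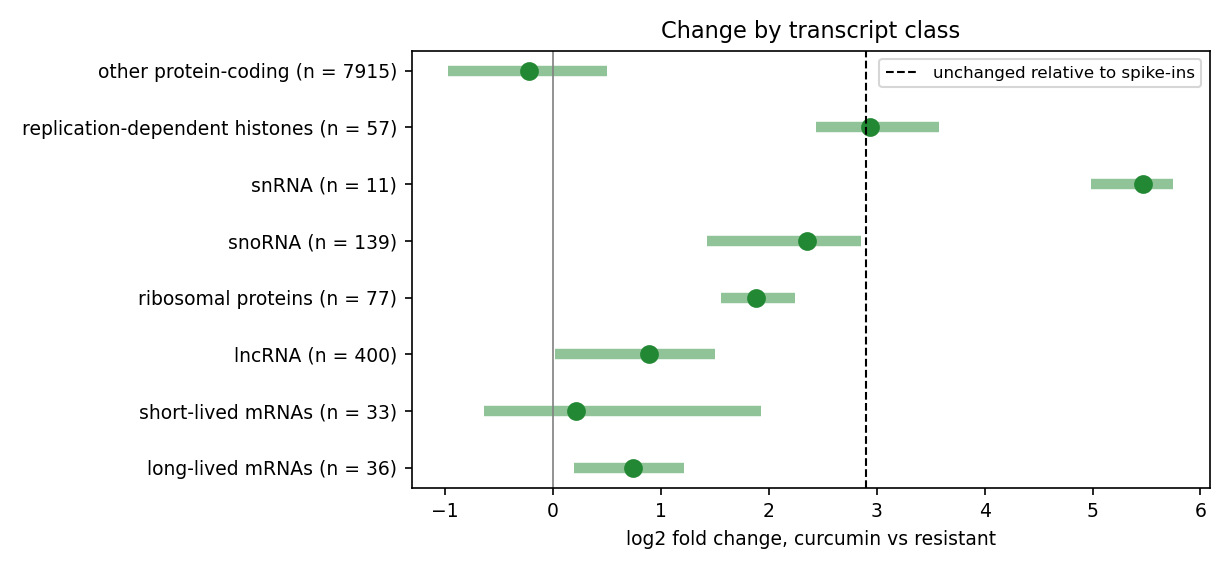
Log2 fold change (horizontal axis), curcumin-treated against resistant cells, by RNA class for the n genes in brackets that were well above background on all 8 arrays: points give the median, bars the quartiles. The dashed line marks no change relative to the spike-ins, 2.90 on this scale; histone genes lie on it at 2.94 and other protein-coding genes at -0.23.

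The split into rises and falls depended on the scaling. The share of calls that were higher, 43.9% here, was 55.5% with median centring, 82.1% with normexp and 1.295% with scaling to the spike-ins, under which 18143 of 18381 called genes were lower. The median of all genes was -0.16 here, 0.14 with median centring, 0.98 with normexp and -3.06 relative to the spike-ins, under which even the heat shock median fell to -1.08. With the slide as a block 13143 genes passed, and within slides 1 and 2 alone (2 arrays against 2 each) 10219 and 10384. The 7 lists called were again within the range of other groupings of the arrays, up to 9.

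The comparison of curcumin-treated resistant with parental cells asks how far the treated cells differ from the starting line. NDRG1, a stress-induced gene, was 22.6-fold lower (log2 fold change -4.50, SE 0.50, adjusted p = 1.4e-05), AKR1C3, an aldo-keto reductase, 15.1-fold and CHAC1 14.7-fold lower (-3.88). RNU6ATAC was 267-fold, VTRNA2-1 195-fold and the small non-coding RNA SNAR-F 94.9-fold higher. Leaving out 1 array moved CHAC1 between -4.97 and -3.03, NDRG1 between -5.20 and -3.75 and VTRNA2-1 between 6.76 and 8.05 log2 units. Of 17 heat shock genes 13 rose (camera adjusted p = 0.00204; adjusted p = 0.416 with an estimated correlation), and so did 7 of 9 metallothionein-list genes (0.00903; adjusted p = 0.416 with an estimated correlation). In limma's test 11863 genes passed, 5504 higher and 6359 lower, 7887 changed at least 2-fold, and 9468 had signal above background.

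Of the other lists called here, 14 of 23 ATF4 stress genes fell and 1 rose (camera adjusted p = 0.00903; adjusted p = 0.764 with an estimated correlation), and 13 of 19 endoplasmic reticulum chaperones fell and 1 rose (0.0401; adjusted p = 0.764 with an estimated correlation). Of 16 hypoxia genes 11 fell and 1 rose (0.0148; adjusted p = 0.723 with an estimated correlation), of 19 MAP kinase output genes 12 fell and 2 rose (0.0189; adjusted p = 0.536 with an estimated correlation), and of 19 epithelial genes 10 fell and 1 rose (0.0148; adjusted p = 0.416 with an estimated correlation). Of 13 drug efflux transporters 7 fell (0.0214; adjusted p = 0.416 with an estimated correlation), with a median that turned to 1.23 under normexp. Of 33 DNA replication genes 16 rose (0.00903; adjusted p = 0.764 with an estimated correlation), and of 20 ribosome biogenesis genes 9 rose and 1 fell (0.0271; adjusted p = 0.764 with an estimated correlation). Adjusted over the list alone, the counts that differed were 13 for DNA replication, 8 rises for ribosome biogenesis and 2 rises among the chaperones. Of 27 alternatives, 6 lost the chaperone call, and 6 lost and 1 turned that of ribosome biogenesis. That of DNA replication was lost in 4 and turned in 2, and those of heat shock and drug efflux were each lost in 4. The other calls were lost in 1 to 3. The share of calls that were higher, 46.4%, was 56.5% with median centring, 84.9% with normexp and 1.301% relative to the spike-ins. With the slide as a block 11827 genes passed, on slide 1 alone 8888 and on slide 2 alone, with 1 parental array, 7266.

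Whether curcumin turned the changes of resistance back was asked by setting the first and the second comparison side by side. Of the 1871 genes that differed between resistant and parental cells, 1290 (68.9%) changed the opposite way after curcumin and 159 the same way. Genes low in resistant cells and higher after curcumin included FOS, FOSB (-3.88, then 3.75), JUN, HSPA1B and EGR2 (-2.95, then 4.90). Genes high in resistant cells and lower after curcumin included PCK2, MST1 (2.04, then -3.34), ELAC1 (2.07, then -1.86, the first 1.39 to 2.79 without 1 array and its call lost in 9 of 26 alternatives), NALT1 (1.79, then -2.85) and CYB5D2 (1.64, then -1.67). Under normexp the calls of the falls of ELAC1 and CYB5D2 after curcumin were lost. Over the alternatives these falls were as small as -0.33 and -0.15. An opposite change was not always a return to the parental level. Mean scaled signal went beyond it for HSPA1B (4.94 after curcumin, 2.21 in parental cells), EGR2 (-0.86, -2.81) and FOS (1.45, 0.40). The same held for PCK2 (-3.58, -2.66), MST1 (-3.23, -1.93), JUN and NALT1. FOSB (-1.45, -1.32), ELAC1 (-4, -4.21) and CYB5D2 (-4.08, -4.05) ended near it. Treated and parental cells still differed in 11863 genes. In all, 812 genes were up and then down and 478 down and then up. These counts are relative to the bulk of the genes on each array. They were not taken with scaling to the spike-ins, under which nearly all genes called after curcumin were lower.

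Both comparisons use the same resistant arrays, which makes opposite changes by chance. Independent lists of these sizes would share 670.07 genes in opposite and 635.74 in the same direction. With the resistant arrays split 2 and 2 between the comparisons, in all 6 ways, 292 to 591 genes were called in resistance (440 on average), of which 205 to 411 were reversed (303 on average) and 25.3 on average went the same way. The correlation of the fold changes across genes, which are not independent replicates, was -0.33 on average over the splits, -0.36 with all 4 arrays in both and -0.46 in simulated unchanged groups. The covariance was -0.29, -0.30 and -0.03, a difference of -0.27 between all 4 arrays and the simulation. Among genes well above background on every array, 514 were higher and 411 lower in resistance, of which 670 were reversed and 85 changed the same way. The reversed count was 480 without resistant replicate 3, 688 without resistant replicate 4, 726 without resistant replicate 2 and 747 without parental replicate 2. It was 1091 with the slide as a block, 52 on slide 1 alone and 0 on slide 2 alone, where no gene passed the first comparison.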

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

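The search for arrays far from the rest of their group was planned; the tests of the dim curcumin arrays, of parental replicate 1 and of the shared resistant arrays were chosen after these results were seen. In groups of 4, an array was singled out where its gap to the nearest other array exceeded the critical share of the group's range. Of 192 groups, of genes named in the text and of array statistics, 17 were singled out, where chance (1 in 20) gives 9.6.

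Among the resistant arrays, replicate 1 lay apart for DDIT3 (0.29, others 0.75 to 0.81), DNAJA1 (-1.60, others -1.19 to -1.16), EGR1 (0.58, others 0.83), NALF1-IT1 (-4.25, others -4.57 to -4.53) and NDRG1 (0.22, others 0.65 to 0.74). Replicate 2 lay apart for GCLC (-0.51, others -0.14 to -0.07) and HSPA1A (-8.61, others -7.21 to -7.00), replicate 3 for CYB5D2 (-2.03, others -2.59 to -2.50) and MT1L (-0.21, others 0.35 to 0.43), and replicate 4 for CEACAM5 (-9.60, others -7.51 to -7.10). All are scaled log2 signals.

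Among the curcumin arrays, replicate 4 lay apart for AKR1B10 (-6.10, others -7.19 to -7.11), DDIT3 (-3.51, others -2.86 to -2.75), FOS (0.98, others 1.57 to 1.68) and FOSB (-2.93, others -1.03 to -0.90). It is also the array with the lowest gene signal, 7.96 against 8.61, 8.67 and 8.94. Replicate 1 lay apart for RNU6ATAC (2.12, others 2.37 to 2.39), and replicate 2 for SNAR-F (3.92, others 2.71 to 2.72) and VLDLR (-5.95, others -5.21 to -5.15).

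The dim gene signal of the curcumin arrays came with little change in the spike-ins (-0.068 log2 units against resistant and -0.29 against parental arrays). This argues against weaker labelling, hybridisation or scanning or a place on the slide as the whole cause of the dimness. Effects of place on single genes cannot be separated from the groups. Less total RNA in the labelling, as the only change, would lower all classes alike. Yet histone transcripts, a class defined after the data were seen, changed by 0.0364 relative to the spike-ins at the median. Less total RNA together with a difference between classes stays open and was not tested. Histone transcripts lay 3.17 log2 units above other protein-coding genes, the observation from which a loss of polyadenylated RNA sparing RNAs without a tail was drawn, so it does not test that loss. Sparing alone leaves open why small nuclear RNAs lay 2.57 and the measured vault RNA 4.53 above the spike-ins, and why the polyadenylated ribosomal protein mRNAs lay only 1.02 below them, against 3.13 for other protein-coding genes. A stop of transcription before the harvest cannot be told apart from other causes, since short-lived mRNAs lay 0.439 above other protein-coding genes with members going both ways. Of 36 long-lived mRNAs 25 rose and 4 fell relative to the bulk of the genes. Their median was 0.737 (quartiles 0.193 to 1.21), against -0.227 for other protein-coding genes. Curcumin itself, RNA degradation and toxicity at this dose stay open and were not tested. How the labelling reads RNAs without a poly(A) tail was not tested either.

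The higher ATF4 and endoplasmic reticulum chaperone lists in resistant cells may rest on parental replicate 1, since without it their camera adjusted p was 0.405 and 0.324. The median gap between the resistant mean and this array was 1.79 over ATF4 genes and 1.13 over chaperones, against 0.32 and 0.83 for parental replicate 2 and 0.17 and -0.19 for replicate 3. The lower heat shock list does not rest on it (adjusted p = 1.59e-10 without it; gaps of -0.78, -0.82 and -0.86). Whether the array or its culture differed was not tested, and resistance itself stays open.

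The opposite fold changes of resistance and curcumin may in part come from the resistant arrays used in both. With these split between the comparisons the covariance was still -0.285 on average, against -0.0328 in simulated unchanged groups, so the shared arrays do not account for all of it. A response to curcumin stays open as a hypothesis, and so does the cause of the dim arrays, which moves with the same groups.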

How the results depend on the processing

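Alternatives added after seeing the data were the spike-in scaling, the percentile over all probes and the counts with signal above background; the others were planned. Of 3525 values of named genes under alternatives, 3317 kept their direction and side of the threshold, 141 fell below it, 62 passed it and 5 turned. Of 2265 list values, 2063 were kept, 97 lost, 88 gained and 17 turned. Array signal over background limits the curcumin arrays most, since genes under background there have only bounds. Where no cause is named below, the cause was not tested.

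For resistant against parental cells (1871 genes, 973 at least 2-fold, 7 lists), an adjusted p under 0.01 left 425 genes and a 1.5-fold threshold 1763. Quantile normalization gave 1215 genes (1215 with signal above background) and 530 at least 2-fold, normexp 338 at least 2-fold and the authors' values 222. With no filter 920 genes passed, 705 with signal, and with only genes above background everywhere 281 at least 2-fold. Slide 1 alone, with fewer arrays, gave 69 on all 3 counts. Slide 2 alone holds 1 parental array. There these calls were lost while many in curcumin against parental cells were kept. That comparison had more genes changed at least 2-fold (7887 against 973 with all arrays), so it cannot tell whether too few arrays caused the loss. At an unadjusted p under 0.05 the main limma fit had 5230. Only the groups compared gave 4 lists and array weights 3. Leaving out 1 replicate gave 677 to 2852 genes, 676 to 2849 with signal, 523 to 1544 at least 2-fold and 3 to 9 lists.

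For curcumin against resistant cells (13183, 8918 at least 2-fold, 7 lists), no filter gave 40085 and 35606 of more genes tested, and 21 lists. Only genes above background everywhere gave 7865, 4493 and 3 lists from fewer genes. The authors' values gave 5103 at least 2-fold, scaling to the spike-ins 17814, normexp 12 lists and slide 2 alone 12. Leaving out 1 replicate gave 12300 to 13865 genes, 9893 to 11005 with signal, 8654 to 9193 at least 2-fold and 6 to 8 lists. For curcumin against parental cells (11863, 7887, 10 lists), no filter gave 38744, 34600 and 21 lists, genes above background everywhere 7382, 4060 and 6 lists, the authors' values 4478 at least 2-fold and the spike-ins 18290 and 17676. Slide 1 alone gave 6 lists and slide 2 alone 7266 genes, 6210 with signal. Leaving out 1 replicate gave 10990 to 12290 genes, 8786 to 9974 with signal, 7526 to 8587 at least 2-fold and 8 to 12 lists. With an estimated correlation 0 lists were called in each comparison.

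The 1290 reversed genes were 205, 403, 207, 283, 311 and 411 in the splits of the resistant arrays (1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, 3 and 4 against parental), 848 with quantile normalization, 605 with no filter, 52 on slide 1 and 0 on slide 2, and 480 to 1608 without 1 replicate. The correlation of -0.333 was -0.361 with all 4 arrays in both, -0.297 with quantile normalization, -0.231 with normexp, -0.0966 with no filter, -0.305 with the slide block, -0.245 on slide 2 and -0.391 to -0.232 without 1 replicate.

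Replicate numbers are shared between groups, but the labels do not say that they pair samples. Same-numbered arrays, all on the same slide, deviated together weakly at most (r from -0.0439 to 0.19 over 10 pairs, median 0.0464). The median was 0.0183 for other pairs on the same slide and -0.0212 for pairs on different slides. Most arrays, though not all, correlated best with an array of their own number. Weak pairing therefore cannot be excluded, and the numbers were used as a block only as an alternative. With the replicate block 1120 genes (1120 with signal) passed in resistant against parental, 13090 and 11493 in the other comparisons, 822 genes were reversed and the correlation was -0.289.

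Under normexp, which adds an offset that lifts dim genes on dim arrays, the curcumin against resistant change turned to 1.19 for ABCB4, 0.97 for ABCC6, 0.33 for VLDLR, 0.93 for EDEM1 and 0.12 for SLCO1B3. List means are given where the camera direction against other genes turned. For curcumin against parental under normexp they were 0.993 for DNA replication and 0.202 for housekeeping. With no filter, which adds genes under background, they were 0.776 for DNA replication, 0.453 for mitosis, 0.249 for DNA repair, 0.581 for NF-kB and 0.678 for ribosome biogenesis in curcumin against resistant, and 0.777, 0.484, 0.441, 0.665 and 0.215 for DNA replication, mitosis, DNA repair, ribosome biogenesis and housekeeping in curcumin against parental. For resistant against parental on slide 2 they were -0.175 for chaperones, 0.764 for DNA replication, 1.30 for mitosis and 0.651 for cholesterol synthesis, and DNA replication had 0.468 without parental replicate 1. Without parental replicate 3 its camera direction was kept, with a mean of -0.373.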

Other observations

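The counts of genes and lists in other groupings were planned before their results were seen; the classes in RNA-processing terms, the counts of groupings for single lists and the lists of short-lived and long-lived mRNAs were chosen after the data were seen.

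After curcumin several groups of genes not yet described split between rises and falls. For comparison, of all 18889 genes tested 6492 fell and 4003 rose with signal above background. Of 19 epithelial genes 11 fell and 3 rose: CLDN4, of tight junctions (-2.55), and ESRP1, a splicing regulator (-2.08), fell while the keratin KRT8 rose by 1.61. Of 19 MAP kinase output genes 13 fell and 4 rose. SPRED1, a feedback inhibitor, was at least 6.99-fold and ETV5 at least 4.90-fold lower, PHLDA1 fell by 3.86, and FOS, JUN, EGR1 (2.51) and FOSL1 (0.92) rose. Of 16 hypoxia genes 8 fell, NDRG1 by 3.32, and 2 rose, ENO1 by 1.21 and LDHA by 0.85. Of 22 interferon-stimulated genes 11 fell, such as IFIT1 (-2.37) and OAS1 (-1.75), and 2 rose, IFITM3 (1.28) among them. Of 18 p53 targets 8 fell, including the death receptor TNFRSF10B (-3.12), and 1 rose, BAX by 1.70. None of these lists passed camera (adjusted p = 0.132, 0.149, 0.243, 0.125 and 0.125), and under normexp the medians of the MAP kinase, interferon and p53 lists turned to 0.39, 0.40 and 0.49. Of 27 alternatives, 4 gained the call of the epithelial list, 3 that of the hypoxia list and 2 each those of the other 3.

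The remaining lists did not pass after curcumin either. Of 15 BCL2 family genes 8 fell, MCL1 by 1.61 and BMF at least 2.52-fold, and 4 rose, PMAIP1 by 1.74 (camera adjusted p = 0.433). Of 12 mesenchymal genes 6 fell and 3 rose, SNAI1 by 4.99 and MMP9 by 2.83 (0.86). Of 17 WNT and stem genes 10 fell, RNF43 by 2.76 and MYC by 1.12, and 4 rose (0.396). Of 23 cholesterol synthesis genes 10 fell and 4 rose (0.594), and of 11 fatty acid synthesis genes 7 fell and 1 rose (0.0788). Of 13 iron and ferroptosis genes 7 fell and 3 rose (0.359), of 20 autophagy and lysosome genes 9 fell and 3 rose (0.86), and of 8 AHR targets 6 fell (0.132). Of 30 mitosis genes 7 rose and 2 fell (0.149), of 27 DNA repair genes 9 rose, PARP1 by 1.85, and 4 fell (0.287), of 19 NF-kB genes 5 fell and 4 rose (0.86), and of 14 intestinal differentiation genes 5 fell and 1 rose (0.433). Of 15 housekeeping genes 7 rose, ACTB by 1.98, and 4 fell (0.246), with a median of 0.04 that was -0.39 with quantile normalization and -0.26 in the authors' table.

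In resistant against parental cells, lists that did not pass held few calls, such as these: IFIT1 and OAS1 rose and IFITM1 fell by 2.08 among interferon genes, SNAI1 fell by 2.56, KRT8 by 1.11 and BTG2 by 0.99, and HRK, EME1, MT1M and SLC11A2 rose by 1.31, 0.94, 1.13 and 0.58. Replication-dependent histone genes fell in 14 of 58 cases (median -0.57 over those measured in both groups) and none rose. Small nucleolar RNAs fell in 54 of 193 and rose in 4, and 16 of 39 short-lived mRNAs fell and 1 rose.

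Markers of other cell types were mostly not well above background. On every parental array, 2 of 15 mammary markers (GATA3 and TRPS1), 1 of 10 fibroblast markers (PDGFRB), 3 of 10 leukocyte markers with a probe (CD14, CORO1A and PTPRC) and 2 of 8 endothelial markers (ESAM and VWF) were. On every curcumin array only CORO1A was. Of the tested ones, GATA3 and TRPS1 changed in opposite directions between resistant and parental cells, and the 4 leukocyte genes had a camera adjusted p of 0.811 there. Of the endothelial markers ESAM rose by 0.93 and VWF had 1.12 (adjusted p = 0.0531), and both rose when adjusted over the list alone.

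Whether arbitrary divisions of the arrays give results as large was asked by refitting each comparison under all 35 splits of its arrays. The number of genes called was reached by 1 of 35 splits, the real one, in all 3 comparisons, the smallest share that 35 splits allow. Splits that mix the groups put the group difference into the spread, which lowers their counts. They therefore cannot exclude chance as the source of these counts, nor tell the groups from their places on the slides. The real counts were 1871, 13183 and 11863, the highest others 1, 0 and 5551. At least 2-fold they were 973, 8918 and 7887, with highest others of 1, 0 and 4372. The high counts of other splits of curcumin and parental arrays came from 3 splits in which curcumin replicate 2, 3 or 4 joined the parental arrays, while the split with curcumin replicate 1 called 0. Why these differ was not tested.

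For the number of lists called, chance could not be excluded: 26, 9 and 9 of 35 splits gave as many, with 7, 7 and 10 in the real splits and 13, 9 and 12 as the highest others. For single lists the lowest number of splits with a camera p as small was 2 of 35, for heat shock in both resistant against parental and curcumin against resistant cells and for epithelial genes in curcumin against parental cells. For ATF4 stress and endoplasmic reticulum chaperones it was 27 and 17 in resistant against parental and 6 and 7 in curcumin against resistant cells. Genes of these lists are correlated (estimated correlation 0.694 for ATF4 stress, 0.643 for chaperones and 0.277 for heat shock), well above the preset 0.01.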
